A study of Mus musculus with 5 samples.

How the data were processed

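The tissue was the anteroventral medial and lateral preoptic area (avMLPA) of 5 mice, dissected from 300 µm sections. The strain was FosTRAP2, in which the Fos promoter drives a drug-dependent Cre recombinase, so that neurons active in a chosen time window can be marked for good. Animals were 6 to 12 weeks old. Nuclei were isolated and 1 10x Genomics library was made per animal. Per the labels, part of the cDNA was also amplified with a primer at the end of mCherry, which enriches transcripts made from an injected virus. What the virus carried, which treatment each animal had and its state when the tissue was taken are not given in the sources used here.

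The deposited table holds raw UMI counts, that is whole numbers of molecules per gene and nucleus, for 44669 nuclei and 30359 genes, plus 1 feature named WPRE. WPRE is a viral element placed in the 3′ end of many vectors, and its UMIs were used as the viral counts. No value was below 0 or fractional, and each nucleus held at least 500 UMIs. Per the submitters' processing notes, Cell Ranger 3.1.0, Seurat 3.1.0 and the build mm10 were used, without a role or an order for each. Filters and the aligner's settings are not given in the sources used here. The deposited annotation gives each nucleus its library and its cluster among 34, and for 28103 neurons a neuron type among 36. It also gives each neuron a call named Transduced and a call named TRAPed, and how these calls were made is not given in the sources used here. Types have numbers and no names. The 5 library names do not pair with the 5 sample titles, so libraries are called by the names in the files (7_42_6, 7_42_8, 7_52_E, 7_52_R and 7_52_T), and nothing here rests on which title belongs to which. No other nuclei were pooled in: 0 columns came from another series.

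Nuclei in the deposited neuron table were taken as neurons and the other 16566 as non-neuronal nuclei. A neuron type was called excitatory when its summed Slc17a6 counts exceeded its Slc32a1 counts and inhibitory otherwise. Clusters outside the neuron table got a name with the ending "like" from fixed marker lists. The list with the largest share of markers at least 2-fold higher than in the other nuclei, each on at least 10 UMIs, gave the name. It needed at least 3 such markers, most of its markers among them, and a clear lead over the next list among the 10 leading genes where both were high. Clusters of under 50 nuclei, clusters with mostly mitochondrial genes among their 10 leading genes, clusters with more markers of another list among those 10, and clusters far below their library's median UMIs without a marker of their own list there stayed unnamed. The markers were fixed in advance, but the rule for naming was adjusted after the clusters had been looked at.

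Raw UMIs were summed per library and arm of a comparison, and a sum needed at least 10 nuclei. Sums were compared with the edgeR quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16, R 4.3.3) with TMM normalization, filterByExpr and the library as a block. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and every adjusted p given for a gene or a type comes from edgeR unless another tool is named. Log2 fold changes are given with their standard error (SE), and levels as CPM (UMIs scaled to a common library total), mean ± SD over libraries. The test shares information on variance between genes, and very small p-values from so few libraries rest on that sharing. They do not measure the spread between libraries, which the SD gives. WPRE was left out of the gene tests. Both arms of a comparison came from the same library. Gene-centred log2 CPM of these sums correlated with r between 0.134 and 0.850 within a library and at most 0.0947 between libraries. The 5 libraries were checked for copies of each other, and the 10 pairs differed by a chi-square per degree of freedom of at least 7.90.

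The comparisons were neurons against non-neuronal nuclei, excitatory against inhibitory neurons, the excitatory type with the highest mean Adcyap1 level against other excitatory neurons, and Transduced against other neurons. The last was repeated against neurons of the same type, with 5 nuclei drawn per positive nucleus (random seed 1) or all where fewer were there. The number of Transduced nuclei per type was compared with edgeR over the 36 types with at least 50 nuclei, without TMM, giving a log2 ratio of shares. Shares of whole classes were compared with an exact two-sided sign-flip permutation test over libraries, which cannot give a p below 0.0625 with 5 libraries. These comparisons, their alternatives and 26 gene lists were chosen before the data were examined. The comparisons of TRAPed neurons with other Transduced neurons were added once the call had been seen in the files. They repeat the Transduced comparisons, over all types, with types matched and by type. In the gene tests library 7_52_T was left out there, since it held 1 TRAPed and Transduced neuron. Lists of interferon response, T cell, B and plasma cell, dendritic cell and erythroid genes were also added then.

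Genes were named in the text by a fixed rule. It takes the 12 largest positive and the 12 largest negative log2 fold changes among genes with an adjusted p under the threshold, a mean log2 CPM of at least 5 and the same direction in every library, leaving out gene models without a proper name and mitochondrial genes. Members of the fixed lists were also allowed, as were the 10 types with the largest log2 ratio. Because the types and classes were made from the same counts, genes that define them are descriptions and not findings, and the gene tests between types are not independent of the clustering. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, once with a preset correlation between genes of 0.01 and once with an estimated correlation, each adjusted over the lists with at least 3 genes tested. Gene positions are from GENCODE vM21 on build GRCm38.

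Alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors within edgeR, no library block, no filter on low counts, and glmTreat against an absolute log2 fold change of 1. Other alternatives were nuclei with at least 1000 UMIs, nuclei without the 5% with the most UMIs (no doublet caller was run), equal numbers of nuclei per arm, 2 or more viral UMIs in place of the Transduced call, and each library left out in turn. A type-balanced draw from both arms, matching on WPRE UMIs, and TRAPed neurons against all other neurons were added later. Tests were tried on simulated data of the same depth. In the gene tests the changed genes were drawn from those above a floor of expression, and no difference between libraries was simulated. Recovery of weaker genes was not tried. With 50 genes raised 2-fold, the share recovered was 92% for neurons, 100% for excitatory neurons, 54% for the Adcyap1 type, 100% for Transduced neurons with or without matching, 90% for TRAPed neurons and 84% for TRAPed neurons with types matched. With 50 genes lowered 2-fold it was 96%, 100%, 36%, 100% with or without matching, 64% and 50% in the same order, so lower genes were harder to find than higher ones in the Adcyap1 and TRAPed comparisons. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the remaining steps. Intervals of single shares are exact 95% binomial (Clopper-Pearson) intervals, and a count of 0 is given with the limit that 3 counts would make. Intervals and limits cover counting error only. Ambient RNA was not removed, and reads, spliced and unspliced counts and cell states were not analysed here.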

Results

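Single-nucleus RNA was counted in the avMLPA, a preoptic region that holds neurons involved in body temperature and torpor, from 5 mice of 1 group. Each mouse gave 1 library. The libraries held 7439 nuclei (7_42_6), 11553 nuclei (7_42_8), 7081 nuclei (7_52_E), 8225 nuclei (7_52_R) and 10371 nuclei (7_52_T). Their totals ran from 18219228 UMIs in 7_52_E to 24152430 UMIs in 7_42_8, with medians between 1599 and 2916 UMIs per nucleus. Since there is 1 group of animals, the comparisons are between kinds of nuclei of the same libraries.

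Neurons made up 64.2% ± 8.74 of the nuclei (SD, n = 5 libraries). Inhibitory neurons, which use GABA, were the majority, at 75.1% ± 4.96 of neurons, against 24.9% ± 4.96 for excitatory neurons, which use glutamate. The excitatory share was lower by 50.2 percentage points ± 9.92 on average, and lower in 5 of 5 libraries (exact two-sided sign-flip permutation test, p = 0.063, the smallest that 5 libraries allow). The types 24 and 33, counted as inhibitory, held nearly as much Slc17a6 as Slc32a1 (log2 ratios −0.29 and −0.39). Among the other nuclei, oligodendrocyte-like clusters held 13% ± 1.09 of all nuclei and astrocyte-like clusters 8.08% ± 2.58. Oligodendrocyte precursor-like clusters held 3.56% ± 0.547, newly formed oligodendrocyte-like clusters 0.355% ± 0.138, and microglia-like clusters 6.39% ± 5.39. Clusters that the naming rule left without a name held 4.43% ± 6.66, and 3 of them had most astrocyte or oligodendrocyte markers at least 2-fold higher. Of these, cluster 24 also had 6 of 6 pericyte or mural markers higher and was led by Rgs5 and Cldn5, a mural and an endothelial marker. Cluster 20 was led by mitochondrial genes. The unnamed clusters 18, 21 and 25, nearly all from 7_42_8, were led by immune genes, among them Cd3e and Icos, Irf4 and Jchain, and Clec9a and Xcr1, in that order. The large spread of the microglia-like and unnamed shares came from 7_42_8, where they reached 15.8% and 16.1%. The microglia-like nuclei of 7_42_8 were mostly in another cluster than those of the other libraries, with 1775 in cluster 8 and 45 in cluster 11, against 114 and 1202. With nuclei under 1000 UMIs left out the neuron share was 84.0%, since non-neuronal nuclei held fewer UMIs.

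The question of the next comparison was which genes set the neuron table apart from the other nuclei. Neurons held more Kcnip4, a gene for a partner of voltage-gated potassium channels, at 7889 ± 660 CPM against 422 ± 140 CPM (log2 fold change 4.28, SE 0.20, adjusted p = 2.71e-07, higher in 5 of 5 libraries). Cntn5, a cell adhesion molecule of axons, was higher by 4.69 on the log2 scale and the glycosyltransferase gene Galntl6 by 4.64. Snap25, a core protein of synaptic vesicle release, stood at 923 ± 112 CPM in neurons and 166 ± 59.8 CPM in the others. Among the genes lower in neurons were glial and immune genes. Sox10, a transcription factor of the oligodendrocyte lineage, fell by 7.88 on the log2 scale (log2 fold change −7.88, SE 0.33, adjusted p = 1.62e-07). Ikzf1, a blood cell transcription factor also made in microglia, had −7.47, the phagocytosis receptor gene Mertk −7.38, and Aspa, an enzyme of oligodendrocytes, −7.29. Of 17897 genes tested with edgeR, 5910 were higher and 5938 lower in neurons. The pan-neuronal list had 7 of 8 genes higher (7 adjusted over the list alone; camera adjusted p = 0.00100; adjusted p = 0.287 with an estimated correlation). Both the oligodendrocyte list (camera adjusted p = 2.73e-05; adjusted p = 0.250 with an estimated correlation) and the astrocyte list had 9 of 9 genes lower. The 8 mitochondrially encoded genes tested were also all lower in neurons (camera adjusted p = 6.31e-05; adjusted p = 0.262 with an estimated correlation). Camera called 20 of 25 lists, and 0 of 25 with the estimated correlation, where 2 lists had an unadjusted p under the threshold. The 2 classes were defined on the same counts, so these genes describe the classes.

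Excitatory and inhibitory neurons were compared to ask which peptides, receptors and transcription factors go with each transmitter in this area. Besides Slc17a6, the vesicular glutamate transporter that defines the excitatory class (125 ± 17.1 CPM against 7.30 ± 0.639 CPM), excitatory neurons held more Bdnf, a neurotrophin, at 69.9 ± 27.4 CPM against 3.80 ± 0.361 CPM (log2 fold change 4.14, SE 0.14, adjusted p = 5.45e-10). Adcyap1, which encodes the neuropeptide PACAP, was higher by 4.76 on the log2 scale, at 15.6 ± 3.08 CPM against 0.572 ± 0.230 CPM. Opn5, a gene for a violet-light-sensitive opsin, was higher by 3.07, the fever-linked prostaglandin receptor gene Ptger3 by 1.84, the leptin receptor gene Lepr by 1.77, Nos1 by 1.71 and the estrogen receptor gene Esr1 by 1.06. Samd3 (Ensembl ENSMUSG00000051354, chromosome 10, 26229707 to 26272172 in GRCm38) had the largest log2 fold change of the named genes, 5.45 (SE 0.09, adjusted p = 5.58e-13). The calcium channel subunit gene Cacna2d1 was higher by 2.69, the extracellular matrix gene Reln by 1.83 and the prohormone convertase gene Pcsk1 by 1.83.

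Inhibitory neurons held more of the GABA genes Gad1 (log2 fold change −2.96 for excitatory against inhibitory) and Slc32a1 (−3.00), of which Slc32a1 was used to define the class. They also held more of the transcription factor genes Lhx8 (−4.03), Bcl11b (−3.29), Satb1 (−2.64) and Rarb (−2.46), a retinoic acid receptor. Among the peptides, Nts, which encodes neurotensin, was at 6.70 ± 5.37 CPM in excitatory and 20.1 ± 9.81 CPM in inhibitory neurons (log2 fold change −1.54, adjusted p = 0.000322), and Gal, which encodes galanin, had −1.24. Trpm2, a heat-sensitive channel gene, had −0.43, and the tachykinin receptor gene Tacr1 was not called (−0.12, adjusted p = 0.333). Directions of all these called genes were the same in 5 of 5 libraries. Of 16912 genes tested, 2202 were higher and 2288 lower in excitatory neurons, and without 7_42_8 the counts were 1771 and 1846. The list of thermoregulation and torpor candidates went both ways, with 8 of 14 genes higher and 5 lower (camera adjusted p = 0.183). Monoamine and acetylcholine receptors had 2 of 18 genes higher and 11 lower (camera adjusted p = 0.000364; adjusted p = 0.214 with an estimated correlation), among them the dopamine receptor gene Drd1 (−1.86) and the muscarinic receptor gene Chrm2 (−0.65). Striatal projection neuron genes were lower in 7 of 7 cases (camera adjusted p = 0.000364; adjusted p = 0.430 with an estimated correlation). The GABAergic list, which holds the defining Slc32a1, had 9 of 9 lower (camera adjusted p = 2.81e-09, and 0.200 with an estimated correlation). The cholinergic list had 3 of 4 lower (camera adjusted p = 0.00656, and 0.214 with an estimated correlation). With DESeq2 the counts were 1320 and 1442, and without the library block 917 and 1096.

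The neuron types have no deposited names, and the fixed lists show what several of them express. Type 10, excitatory, had the highest mean level of Opn5 (167 ± 71.0 CPM, n = 5 libraries), Bdnf (197 ± 127 CPM), Ptger3 (101.4 ± 70.3 CPM) and Lepr (35.2 ± 15.9 CPM) among the 36 types. Type 30, also excitatory, had the highest level of Adcyap1 (55.9 ± 9.49 CPM) and of Tacr1 (339 ± 183 CPM). Type 5, excitatory, ranked first for Brs3, a receptor gene linked to energy balance (35.1 ± 14.3 CPM), and for the prolactin receptor gene Prlr (320.0 ± 54.2 CPM). It ranked second for Opn5 (36.8 ± 8.41 CPM) and for Lepr (25.8 ± 8.46 CPM). Nts (148 ± 107 CPM) and Gal (45.0 ± 18.4 CPM) peaked in type 15, and Esr1 in type 34 (437 ± 157 CPM, n = 4 libraries), both inhibitory. Chat, the gene for the acetylcholine-making enzyme, peaked in type 25 (668 ± 44.2 CPM) and Gnrh1 in type 33 (200 ± 109 CPM). The dopamine receptor genes Drd1 (type 0, 173 ± 48.0 CPM) and Drd2 (type 19, 228 ± 12.7 CPM, n = 4 libraries) marked different types. Qrfp, the gene for a peptide linked to a torpor-like state, was near the floor everywhere, with a highest mean of 2.39 ± 5.35 CPM in type 33. These levels were ranked and not tested, because the types were made from the same counts.

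Type 30 was compared with the other excitatory neurons because Adcyap1 is a candidate marker of torpor neurons, and Adcyap1 itself picked the type. It held 219 nuclei, 33 to 56 per library, and the next highest type for Adcyap1 was type 10 (33.6 ± 16.5 CPM). Type 30 stood out by Ebf1, a transcription factor gene (Ensembl ENSMUSG00000057098, chromosome 11, 44617317 to 45008091 in GRCm38), at 1588 ± 228 CPM against 19.3 ± 2.42 CPM (log2 fold change 6.35, SE 0.13, 5 of 5 libraries). Necab1, a gene for a neuronal calcium-binding protein, was higher by 3.74 on the log2 scale and Stac by 3.50. The substance P receptor gene Tacr1 was higher by 3.25, at 352 ± 216 CPM against 35.6 ± 10.6 CPM (adjusted p = 1.24e-76). Reln, at 1336 ± 444 CPM against 323 ± 72.0 CPM, was higher by 2.04. Lower genes included Fam19a1, a secreted protein gene (−3.88, 77.9 ± 36.5 CPM against 1167 ± 63.4 CPM), Prlr (−3.57), the axon guidance genes Slit3 (−3.40), Slit2 (−3.25) and Sema3c (−5.03), and the glycine receptor gene Glra3 (−3.11). Tcf7l2 and Lncenc1 had 0 UMIs in type 30 and 845 UMIs each in the other excitatory neurons, at least 8.18-fold lower with 3 counts over the group taken as the floor. The other excitatory neurons are a mix of types, so a lower gene may mark another type more than it sets type 30 apart. Tcf7l2 peaked in the excitatory type 22 at 394 CPM and was above 10 CPM in only 3 of the neuron types.

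Of 15 fixed lists camera called 2 in type 30, and 0 with an estimated correlation. Adcyap1, which picked the type, is a member of the fixed lists and was not taken out of them. A list that holds it is therefore not independent of that choice. The fever receptor gene Ptger3 had −3.97 on the log2 scale, Opn5 −2.47 and Esr1 −1.76, and the thermoregulation and torpor candidates, a list that was not called, went both ways, with 3 of 11 genes higher and 4 lower (camera adjusted p = 0.601). Of all neuron types only types 10 and 5 held Opn5 above 10 CPM, so its value describes those types more than type 30. Neuropeptides had 4 of 9 genes higher and 0 lower (5 adjusted over the list alone; camera adjusted p = 0.000755; adjusted p = 0.211 with an estimated correlation), with Scg2 (1.22) and Cartpt (4.12, 69.6 ± 118 CPM against 3.97 ± 2.11 CPM) among them. Immediate early genes, which switch on within minutes of neuronal activity, had 6 of 10 higher (8 adjusted over the list alone, with 1 lower; camera adjusted p = 0.00283; adjusted p = 0.409 with an estimated correlation). Fos was at 64.5 ± 37.4 CPM against 22.5 ± 16.3 CPM (log2 fold change 1.51, SE 0.32, adjusted p = 7.74e-05, higher in 5 of 5 libraries), and Npas4 at 58.0 ± 29.9 CPM against 21.6 ± 12.2 CPM. Library 7_42_8 decided 3 of these: without it the log2 fold change was 0.94 for Nr4a1 (adjusted p = 0.259), 1.54 for Fosl2 (adjusted p = 0.241) and 0.24 for Junb (adjusted p = 0.849), and Junb also lost its call without 7_52_E (0.66). Of 12052 genes tested with edgeR, 439 were higher and 481 lower, against 328 and 416 without 7_42_8. DESeq2 called 369 and 257, and equal numbers of nuclei gave 222 and 198 of 2694 genes tested.

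The virus comparisons ask which neurons had been reached by the injected vector. The Transduced call marked 17424 neurons, 63.5% ± 16.3 of neurons per library (n = 5), from 35.2% in 7_52_T to 76.8%. Excitatory neurons carried the call more often than inhibitory neurons, 75.6% ± 13 against 59.9% ± 16.9, by 15.8 percentage points ± 7.68 and in 5 of 5 libraries (exact two-sided sign-flip permutation test, p = 0.063, the smallest possible). The call and the WPRE counts overlapped in part: 7149 Transduced neurons held 0 WPRE UMIs, and 2699 neurons without the call held at least 1. WPRE was also counted in non-neuronal nuclei, from which ambient RNA was not removed. Its CPM there was 55.5% ± 34.8 of that in neurons, above 7 of 8 pan-neuronal genes, which ran from 6.19% ± 1.97 for Meg3 to 20.1% ± 7.04 for Snap25 and 29.5% ± 12.9 for Stmn2, and below Nefl at 145% ± 124. A WPRE UMI was present in 48.2% ± 20.0 of neurons and in 23.1% ± 10.7 of non-neuronal nuclei, with medians of 3036 and 839 UMIs per nucleus. After thinning each nucleus to 500 UMIs the shares were 20.3% ± 11.2 and 15.4% ± 7.63.

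By type the share, pooled over libraries, ran from 11.4% to 86.9%. The types were not spread evenly over the libraries, so the order of these shares differs from that of the log2 ratios, which have the library as a block. Type 5 was Transduced in 86.9% of its nuclei (log2 ratio of shares 2.38, SE 0.23, adjusted p = 2.52e-05) and type 10 in 84.2% (2.09, adjusted p = 4.85e-05), both excitatory. Type 30 reached 82.2%, the Nts-rich type 15 83.8% and the Esr1-rich type 34 86.6% (1.57, adjusted p = 0.0174). At the other end, type 6, the inhibitory type richest in Tac1 (301 ± 73.4 CPM), was Transduced in 11.4% (−3.53, adjusted p = 2.24e-06), type 26 in 25.2% (−2.03, adjusted p = 5.33e-05), and the dopamine receptor types 19 and 0 in 36.3% and 37.5%. The excitatory type 22 was also called lower, at 49.7% (−0.73, adjusted p = 0.0174). Types 6 and 26 were also the shallowest of the 36, with medians of 1196 and 1961 UMIs against 2888.5 in type 5. Directions were the same in 5 of 5 libraries for types 5, 10, 30, 15, 34, 6, 26, 22 and 0, and in 4 of 5 for type 19. In all, edgeR called 12 types higher and 10 lower of 36. Without 7_52_E there were 7 higher and 5 lower, without 7_52_R 8 and 7, and without 7_52_T 7 and 9. Type 19 lost its call without 7_52_E (−0.87) or 7_52_R (−0.91), and type 34 without 7_52_T (1.38, adjusted p = 0.0517). With 2 or more viral UMIs in place of the call 7 types were higher and 12 lower, type 15 was not called (0.66, adjusted p = 0.210), and type 24 went from 0.77 to −0.13.

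**Figure D1:**
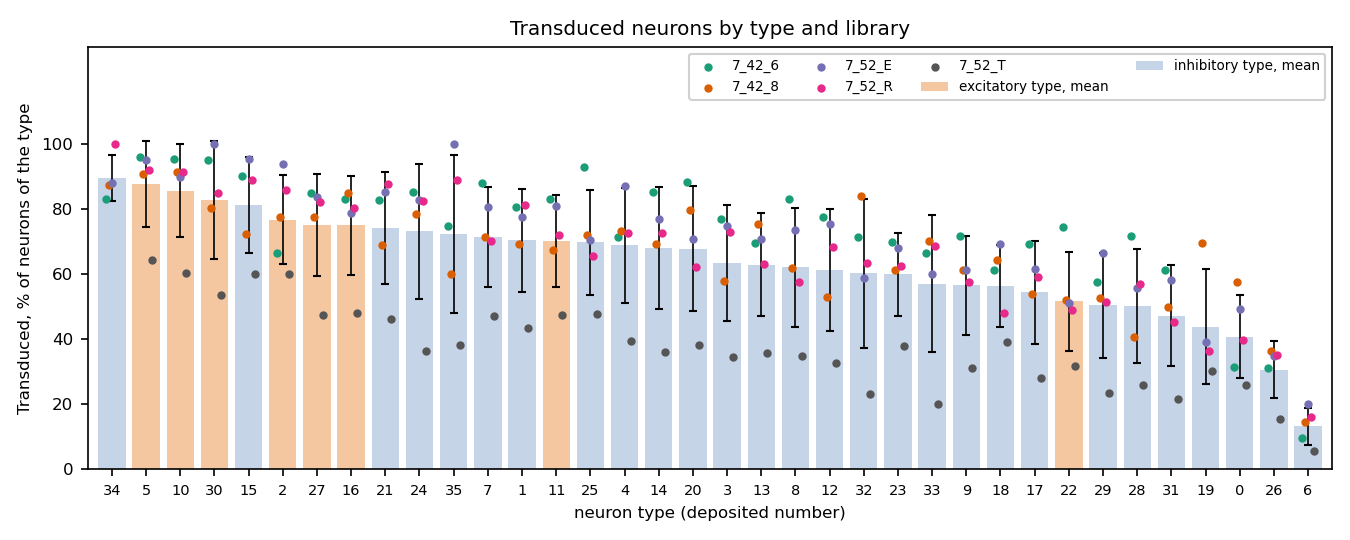
Share of neurons of each deposited type that carried the Transduced call, in percent. Bars are means over the libraries with at least 10 neurons of the type, error bars are the SD and points are single libraries. The excitatory types 5 and 10 stand at the high end and the inhibitory types 6 and 26 at the low end, at 11.4% and 25.2% over all nuclei, while the excitatory type 22 is at 49.7%.

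UMIs counted as Chrm3, a muscarinic acetylcholine receptor gene (Ensembl ENSMUSG00000046159, chromosome 13, 9875486 to 10360847 in GRCm38), were higher in Transduced neurons, at 1458 ± 585 CPM against 477 ± 105 CPM (log2 fold change 1.52, SE 0.19, adjusted p = 7.93e-05, 5 of 5 libraries). Whether they came from the cells' own gene or from a viral transcript stays open. Summed over libraries and types, Chrm3 moved with the viral counts. From 0 to 16 or more WPRE UMIs it went from 547 to 4332 CPM in excitatory and from 569 to 3039 CPM in inhibitory neurons. In non-neuronal nuclei it went from 73.0 CPM at 0 to 1086 CPM at 4 or more. Bdnf was at 25.6 ± 8.41 CPM against 8.31 ± 2.57 CPM (log2 fold change 1.59, SE 0.11, adjusted p = 2.19e-07), Adcyap1 at 5.70 ± 1.32 against 1.71 ± 0.511 CPM (1.75), Pcsk1 at 42.9 ± 16.6 against 20.7 ± 7.39 CPM (1.03), and Slc17a6 at 41.0 ± 4.11 against 27.7 ± 6.75 CPM (0.59). Opn5 had 1.38, Lepr 0.97 and Ptger3 0.80. The interferon-induced gene Rnf213 had 0.80, and neurons of 7_42_8 held 1494 CPM of an added list of interferon genes against 201 ± 115 CPM in the other 4 libraries. Actb, the cytoplasmic actin gene, had 0.92, but with 2 or more viral UMIs in place of the call it had −0.35 (adjusted p = 0.00277). Lower genes were the transcription factor genes Rreb1 (−1.67, 20.1 ± 3.40 against 64.6 ± 14.9 CPM, adjusted p = 3.82e-10), Meis2 (−1.18) and Rarb (−1.09), the synaptotagmin gene Syt6 (−1.48), the growth factor gene Mdk (−1.35) and Gng7 (−1.03).

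As groups, thermoregulation and torpor candidates had 9 of 14 genes higher in Transduced neurons and 0 lower (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.78e-07; adjusted p = 0.157 with an estimated correlation). Striatal projection neuron genes were lower in 7 of 7 cases (camera adjusted p = 0.000376; adjusted p = 0.530 with an estimated correlation), among them Drd1 (−1.21) and Adora2a (−1.43, 4 of 5 libraries). Immediate early genes had 8 of 14 higher (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00412; adjusted p = 0.606 with an estimated correlation). Among these Ier2 had 1.30 and Btg2 1.06, and Fos had 0.87 in 4 of 5 libraries, without a call when 7_52_R was left out (0.57, adjusted p = 0.0700). Mitochondrially encoded genes, a sign of RNA from outside the nucleus, were lower in 8 of 8 cases (camera adjusted p = 1.80e-09; adjusted p = 0.157 with an estimated correlation), mt-Co3 by −0.47. The other calls were GABAergic genes with 4 of 9 lower (camera adjusted p = 0.0182; adjusted p = 0.530 with an estimated correlation), astrocyte genes with 3 of 8 lower (0.00251; adjusted p = 0.157 with an estimated correlation), and thermosensitive and leak channels with 7 of 21 higher and 1 lower (0.0250; adjusted p = 0.234 with an estimated correlation). Of 16732 genes tested with edgeR, 1086 were higher and 1258 lower, 541 and 691 without 7_52_R, and 826 and 1070 without 7_42_8. DESeq2 called 429 and 574. Without the library block edgeR called 10 and 11. The type mixes of the arms differed by 23.4% to 34.7% within a library. That is the share of an arm's nuclei that would have to change type for both arms to have the same mix.

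**Figure D2:**
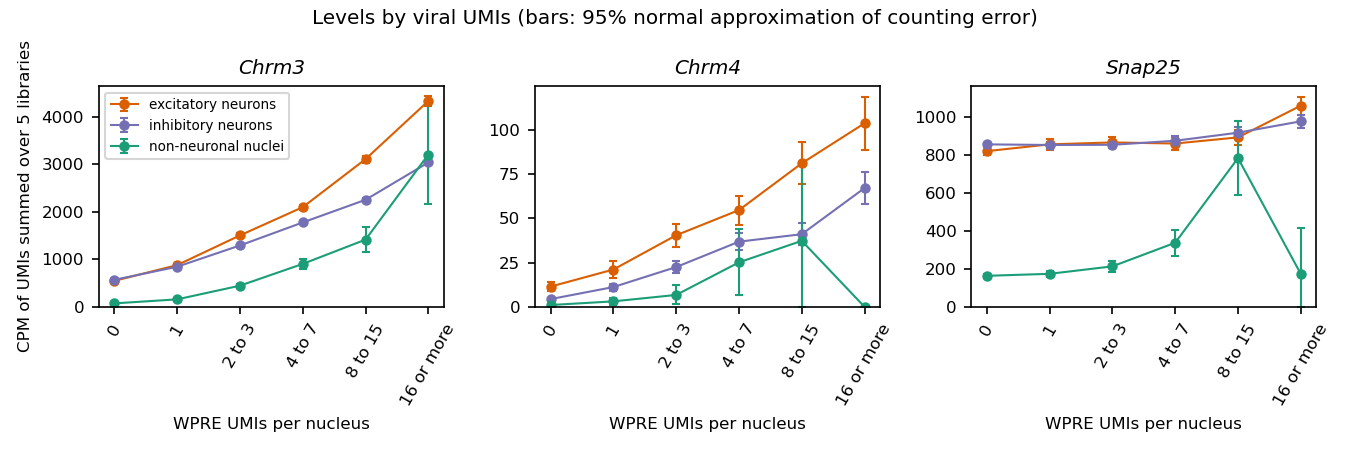
Levels of Chrm3, Chrm4 and Snap25 in CPM by the number of WPRE UMIs per nucleus, summed over 5 libraries, for excitatory neurons, inhibitory neurons and non-neuronal nuclei. Bars are a 95% normal approximation of the counting error. Chrm3 in excitatory neurons goes from 547 CPM at 0 to 4332 CPM at 16 or more WPRE UMIs.

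The same comparison against neurons of the same type asked what stays when the mix of types is held equal. Chrm3 (log2 fold change 1.51, SE 0.20, adjusted p = 0.000176), Adcyap1 (1.73), Bdnf (1.58) and Pcsk1 (1.01) were higher and Rreb1 (−1.43), Syt6 (−1.30), Mdk (−1.24) and Drd1 (−1.17) lower, each in 5 of 5 libraries. Matching was incomplete, because the draw ran short of nuclei in 175 of 180 combinations of type and library. The type mixes of the arms still differed by 20.2% to 34.6% of nuclei. A draw that balanced the types fully gave 1.22 for Chrm3, 1.11 for Adcyap1, 0.73 for Bdnf and 0.63 for Pcsk1, all still called. Under it Rreb1 had −0.30 (adjusted p = 0.00849), while Syt6 (−0.23), Mdk (−0.21) and Drd1 (−0.03, adjusted p = 0.893) were not called. Actb had 0.95 with matching, 1.12 with full balance and −0.31 with 2 or more viral UMIs, and Rnf213 had 0.80. With the incomplete matching the same 7 of 21 lists were called as in the unmatched comparison, on nearly the same nuclei. Lists were not tested with full balance, so these calls do not show what stays with the types held equal. Called were thermoregulation and torpor candidates with 9 of 14 higher (camera adjusted p = 7.04e-07, and 0.201 with an estimated correlation), immediate early genes with 10 of 14 higher (0.00252, and 0.628 with an estimated correlation), striatal genes with 7 of 7 lower (0.000606, and 0.562 with an estimated correlation) and mitochondrially encoded genes with 8 of 8 lower (3.68e-09, and 0.201 with an estimated correlation). The other lists were astrocyte genes (3 of 8 lower), GABAergic genes (4 of 9 lower) and thermosensitive and leak channels (5 of 21 higher and 1 lower), with camera adjusted p of 0.00252, 0.0176 and 0.0309, and adjusted p of 0.201, 0.473 and 0.254 with an estimated correlation. Of 16720 genes, 1034 were higher and 1188 lower, 769 and 993 without 7_42_8, and 482 and 603 in the lowest case with 1 library left out. With full balance 795 were higher and 522 lower, DESeq2 called 382 and 501, and without the library block edgeR called 6 and 6.

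The TRAPed call bears the name of the strain's method, which marks neurons by activity of the Fos promoter, but how the call was made is not given in the sources used here. The TRAPed comparisons ask which Transduced neurons carried it. There were 343 TRAPed neurons, of which 317 were also Transduced and 26 were not. They made up 1.69% ± 1.40 of Transduced neurons (n = 5 libraries): 78 of 3983 in 7_42_6, 141 of 3848 in 7_42_8, 70 of 3374 in 7_52_E, 27 of 3851 in 7_52_R and 1 of 2368 in 7_52_T. The share was 2.37% ± 1.76 in excitatory and 1.40% ± 1.29 in inhibitory Transduced neurons, higher in excitatory neurons in 4 of 5 libraries (exact two-sided sign-flip permutation test, p = 0.125). Without type 5 the excitatory share was 1.33% ± 0.965, higher than the inhibitory one in 2 of 5 libraries, and over all nuclei 61 of 4170 excitatory (1.46%) and 180 of 12169 inhibitory neurons (1.48%) were TRAPed. Type 5 was left out because it had the highest share, which lowers the excitatory share by construction. Type 5, the excitatory type that ranked first for Brs3 and Prlr, held 76 TRAPed neurons among 1085 Transduced ones, or 7.0% (exact 95% interval 5.56 to 8.69). After taking out library and WPRE UMIs, 35.9 TRAPed neurons were expected in it. Its log2 ratio of shares was 2.03 (SE 0.39, adjusted p = 0.00484, 4 of 5 libraries), and without 7_52_E it was 1.84 and no longer called (adjusted p = 0.0581). Type 10, which ranked first for Opn5 and Lepr, had 14 TRAPed neurons and 1.54%, and was not called (log2 ratio −0.27, adjusted p = 0.691).

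Type 16, excitatory and rich in Nos1 (149 ± 24.8 CPM), was lower, with 1 TRAPed neuron among 597 (0.168%, exact 95% interval 0.00424 to 0.930; log2 ratio −3.58, adjusted p = 0.00484). Type 9 had 3 among 610 (0.492%; −2.01, adjusted p = 0.0339). Type 0, the Drd1 type, had 0 among 741, which allows a share of up to 0.405% (adjusted p = 0.00716), and type 12 had 0 among 584, which allows up to 0.514% (adjusted p = 0.00656). All 4 of these lost their call without 7_42_8, where edgeR called 1 type higher and 0 lower and 7 types had an unadjusted p under the threshold. Type 0 also lost its call without 7_52_E (adjusted p = 0.0551), and type 9 when any single library was left out (adjusted p from 0.0581 to 0.139). The Adcyap1 type 30 had 7 among 180 (3.89%, exact 95% interval 1.58 to 7.85), not called (1.06, adjusted p = 0.194). In total edgeR called 1 type higher and 4 lower of 36, and with 2 or more viral UMIs 1 higher and 0 lower, with 5 types at an unadjusted p under the threshold. There were 7 types with 0 TRAPed neurons, and the limits that allows ran from 0.405% to 3.41%. On simulated data of the same size 82.5% of types with 3-fold odds were recovered.

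**Figure D3:**
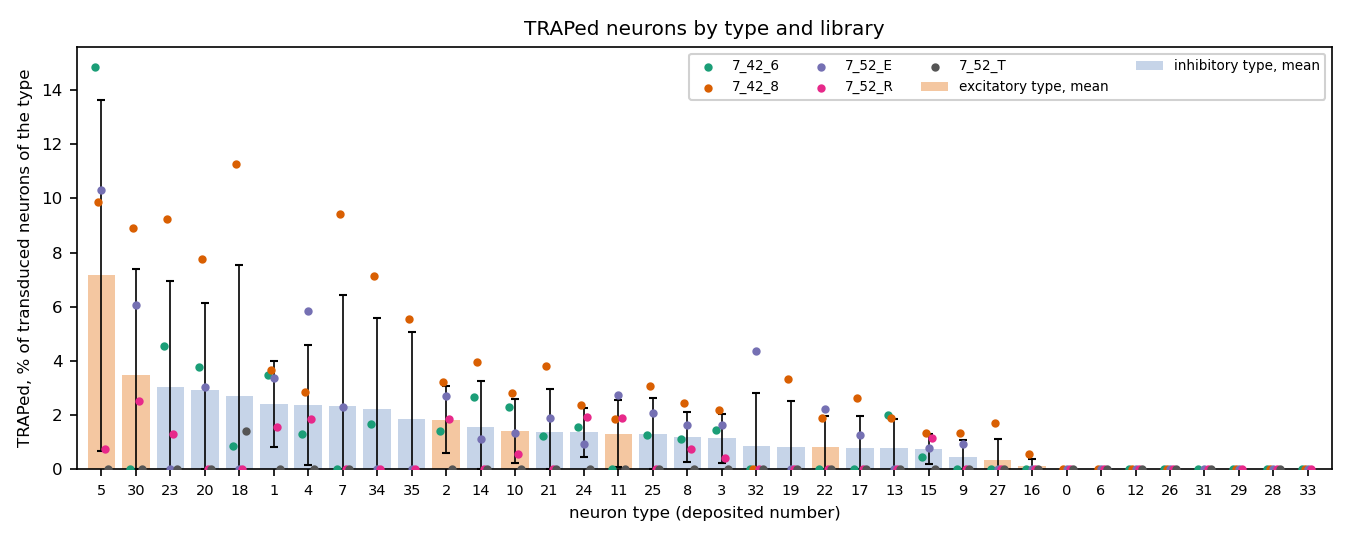
Share of Transduced neurons of each deposited type that were TRAPed, in percent. Bars are means over the libraries with at least 10 Transduced neurons of the type, error bars are the SD and points are single libraries. Type 5, at 7.0% over all nuclei, is the only type called higher.

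TRAPed neurons were then compared with other Transduced neurons in the 4 libraries with at least 10 of them. Most of the immediate early genes tested were higher. Junb, a member of the AP-1 transcription factor family (Ensembl ENSMUSG00000052837, chromosome 8, 84974484 to 84978718 in GRCm38), stood at 247 ± 170 CPM against 53.1 ± 28.8 CPM (log2 fold change 2.10, SE 0.15, adjusted p = 2.02e-38, 4 of 4 libraries). Fos, the gene the strain is built on (Ensembl ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), was at 83.5 ± 58.0 against 22.1 ± 13.7 CPM (1.81, adjusted p = 6.34e-11). Btg2 had 1.85, Nr4a1 1.41, Npas4 1.47 and Fosb 2.41 (3 of 4 libraries). Homer1, whose short form is made on activity, was at 345 ± 181 against 112 ± 46.0 CPM (1.51), and the granule protein gene Vgf was higher by 1.41, Pcsk1 by 1.59, Scg2 by 0.81 and Bdnf by 1.38. The histone deacetylase gene Hdac5 had 1.12, the kinase gene Hunk 1.14 and Sipa1l2 1.22. Chrm3 (0.85) and Chrm4 (1.02) were also higher. Summed over libraries and types, these 2 genes moved with the viral counts, and so did Fos and Junb. From 0 to 16 or more WPRE UMIs in excitatory neurons Fos went from 10.9 to 68.6 CPM and Junb from 31.8 to 165 CPM. In inhibitory neurons Fos went from 8.72 to 47.8 CPM and Junb from 27.0 to 117 CPM. Homer1 was higher only at 16 or more WPRE UMIs, at 215 CPM in excitatory and 172 CPM in inhibitory neurons, against 95.3 to 118 CPM and 87.6 to 108 CPM from 0 to 15. Libraries differed in WPRE, from 111 CPM in neurons of 7_52_T to 1742 CPM in those of 7_52_E. Differences between libraries or types may therefore be part of these trends, which was not tested. Lower genes were Rarb (−1.50, 25.3 ± 10.8 against 89.3 ± 43.4 CPM), Eml1 (−1.36) and Zfpm2 (−0.87), each in 4 of 4 libraries. Meis2 had −1.06 and lost its call without 7_52_E (−0.76). Neither Rarb nor Meis2 was among the lower genes that the fixed rule named with the types matched.

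The immediate early gene list had 12 of 14 genes higher (12 adjusted over the list alone; camera adjusted p = 1.25e-17; adjusted p = 0.198 with an estimated correlation), with Nr4a2 (0.81) and Egr3 (1.25) not called. Arc (2.09, 3 of 4 libraries) lost its call without 7_42_8 (2.07), 7_52_E (2.13) or 7_52_R (1.87), and Egr1 (1.37) without 7_52_R (1.02). Neuropeptides had 3 of 16 higher (5 adjusted over the list alone, with 1 lower; camera adjusted p = 0.414). Nts, one of them, rested on 7_52_R: it had 1.23 in 3 of 4 libraries and 0.10 without that library. Of 15487 genes tested, 129 were higher and 97 lower with TMM, and 164 and 73 with DESeq2 size factors. Without 7_42_8 the counts were 106 and 106. DESeq2 called 67 and 17, and edgeR without the library block called 0 and 0, with 1178 genes at an unadjusted p under the threshold. TRAPed nuclei were deeper, with medians of 3222 to 4463.5 UMIs against 2868 to 3736 in the same libraries. The type mixes of the arms differed by 33.2% to 48.3% of nuclei.

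With the types matched, 5 other Transduced neurons of the same type and library per TRAPed neuron, 9 immediate early genes had enough counts to be tested. Junb was at 284 ± 217 against 67.3 ± 41.5 CPM (log2 fold change 1.92, SE 0.16, adjusted p = 5.14e-17, 4 of 4 libraries), Fos at 95.9 ± 73.2 against 27.1 ± 16.9 CPM (1.62, SE 0.24, adjusted p = 1.07e-06) and Homer1 at 388 ± 210.5 against 110 ± 53.5 CPM (1.56). Btg2 had 1.51, Nr4a1 1.25, Vgf 1.16, Hdac5 1.11 and Scg2 0.61. Fosb had 1.86 in 3 of 4 libraries and Npas4 1.42, the latter without a call when 7_52_E was left out (1.01, adjusted p = 0.170). Immediate early genes were higher in 9 of 9 cases (9 adjusted over the list alone; camera adjusted p = 1.26e-14; adjusted p = 0.292 with an estimated correlation). Neuropeptides had 3 of 4 genes higher (camera adjusted p = 0.00720; adjusted p = 0.404 with an estimated correlation): Scg2, Vgf and Nts, of which Nts (1.16, 3 of 4 libraries) had 0.43 without 7_52_R (adjusted p = 0.854) and also lost its call without 7_42_6 (1.23, adjusted p = 0.143). Steroid and metabolic hormone receptors had 1 of 11 genes lower (camera adjusted p = 0.000415; adjusted p = 0.292 with an estimated correlation), namely Esr1 (−0.92, 27.4 ± 6.17 against 51.5 ± 4.22 CPM, adjusted p = 0.0487), which lost its call whichever library was left out (adjusted p from 0.0767 to 0.324).

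Fewer genes were lower with the types matched. The lower genes named by the fixed rule ran from −1.25 (Eml1) to −0.50 (Slit2). They included Zfpm2 (−0.59) but not Rarb or Meis2. The lower levels of Rarb and Meis2 are therefore not shown to hold with the types held equal. Eml1 had −1.25 in 4 of 4 libraries, without a call when 7_42_6 was left out (−1.26, adjusted p = 0.0920), and Cdh2, a cadherin gene, had −0.52, without a call when 7_42_6, 7_42_8 or 7_52_E was left out (−0.52, −0.53 and −0.56). Chrm3 was still higher with the types matched (0.69), and 0.29 when nuclei were also matched on WPRE UMIs. That matching, which ran short of nuclei in 53 of 188 combinations, left Junb at 1.40, Fos at 0.99 and Homer1 at 1.22, all called. A draw that balanced the types in both arms left Junb at 1.74 and Homer1 at 1.40, while Fos had 1.05 and was not called (adjusted p = 0.117). Of 7433 genes tested with edgeR, 94 were higher and 21 lower. Without 7_42_8 there were 64 and 10, and without 7_42_6 61 and 2. With WPRE matching 39 were higher and 7 lower, and with the balanced draw 21 and 3. DESeq2 called 34 and 1, and edgeR without the library block 0 and 0, with 361 genes at an unadjusted p under the threshold. The RNA was counted at the time the tissue was taken, and the state of the animals then is not given in the sources used here.

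**Figure D4:**
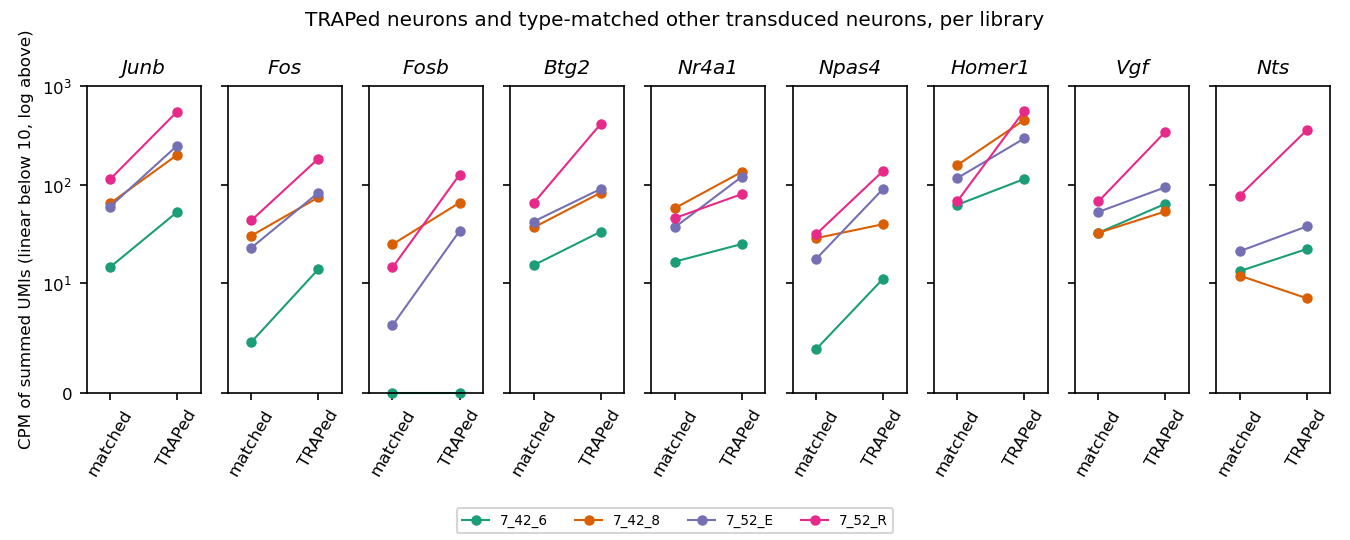
CPM of 9 genes in TRAPed neurons and in other Transduced neurons of matched types, with 1 line per library (linear below 10 CPM and logarithmic above). Junb, Fos and Homer1 are higher in 4 of 4 libraries, and Nts is led by 7_52_R.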

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

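The list of interferon genes and the lists of immune cells were drawn up after the clusters of 7_42_8 had been seen, and the 3 tests of the interferon genes were settled in their present form after their values had been seen. A library is listed here when its gap to the nearest of the other 4, over the range of all 5, was above 0.71. Of 67 measures tested 9 were past that value, while chance alone passes about 1 in 20.

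Library 7_42_8 stood apart in its cells. Neurons made up 49.1% of its nuclei, the lowest of the 5 libraries, while microglia-like clusters made up 15.8% and clusters without a name 16.1%, the highest. In it 6 clusters took over 90% of their nuclei from that library, 4437 of 4574 nuclei, which is 38.4% of 7_42_8 and 0.414% of the other 4 libraries. One of them was the microglia-like cluster 8, with 1775 nuclei from 7_42_8 and 114 from the others. It had 8 of 8 microglia markers higher but 0 among its 10 leading genes, which included Acod1, Cybb and Lyz2. The microglia-like cluster 11, led by Siglech, held 45 nuclei from 7_42_8 and 1202 from the others. Genes of T cells were at 345 CPM over all nuclei of 7_42_8 against 38.9 to 54.4 CPM in the others, genes of B and plasma cells at 319 against 5.99 to 7.45 CPM, and genes of dendritic cells at 297 against 46.7 to 61.3 CPM. Erythroid genes, a sign of blood, were at 35.6 CPM, within the 23.6 to 43.4 CPM of the other libraries.

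Interferon response genes were at 1494 CPM in the neurons of 7_42_8, against 201 ± 115 CPM in those of the other 4 libraries, and at 11636 CPM in its oligodendrocyte-like clusters against 708 ± 564 CPM. The latter values compare mostly different clusters. In 7_42_8 1202 of these nuclei were in cluster 13 and 155 in cluster 1, against 12 and 4395 in the other 4 libraries. The neurons of 7_42_8 were not the shallowest, with a median of 2909.5 UMIs, 1.14 times (95% interval 1.12 to 1.16) the lowest of the other libraries, 2546 in 7_52_T. That met the rule set against shallow nuclei. Their median was still below those of 7_52_R (3062), 7_52_E (3209) and 7_42_6 (3686.5). Since CPM is scaled to the total UMIs, this comparison of depth cannot decide what raised the interferon genes. RNA leaking from the immune nuclei stays open. The excess of the interferon genes, as a share of their level in the immune clusters, had a median of 10.1% (lower quartile 7.11%), against a median of 0.788% and an upper quartile of 4.10% for the immune clusters' own genes. That is 12.8 times the median, above the 3 times set as a match with leaking, and 2.46 times the upper quartile (1.73 to 3.45), below the 3 times that would have argued against it. RNA of all non-neuronal nuclei stays open as well, with a median of 12.7% (lower quartile 8.19%) against a median of 3.11% and an upper quartile of 7.78%, which is 4.09 times the median and 1.64 times the upper quartile (1.05 to 2.01). A response of the neurons themselves, for example to inflammation in that animal, may be part of the pattern and was not tested, since the labels name no such group.

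Library 7_52_T had the fewest Transduced neurons, 35.2% of all neurons and 52.7% of excitatory neurons, both the lowest of the 5 libraries. It had the highest shares of type 25, the Chat-rich type, at 2.33% of neurons and of type 26 at 3.29%. The rarely Transduced types 0, 6 and 19 were also at their highest there, at 12.3%, 8.13% and 4.25% of neurons, against 0.366%, 0.810% and 0.116% in 7_42_6, though not past the value above. Its mean share of mitochondrial UMIs was the highest too, at 1.17%, against 0.895% in 7_42_8 and 0.124% to 0.177% in the other 3.

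WPRE, which was left out of the gene tests as a gene, was counted at 397 ± 228 CPM in non-neuronal nuclei (n = 5 libraries), above the limit that a count of 0 allows, against 964 ± 672 CPM in neurons. The ratio of non-neuronal to neuronal WPRE CPM was 0.360 to 0.416 in 4 libraries and 1.18 in 7_52_T.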

How the results depend on the processing

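The alternatives for the TRAPed comparisons, the type-balanced draw, matching on WPRE UMIs and the comparison with all neurons not TRAPed were chosen after the data had been seen. The 124 gene results named in the text gave 1667 values under the alternatives. Of these 1448 kept their direction and their side of the threshold, 217 kept their direction and lost the call, and 2 changed sign. With DESeq2 size factors 124 of 124 kept both, and with 1 library left out 897 of 956 values for genes, types and shares did. Calls were lost without the library block in 81 of 157 values, and with glmTreat, which asks for a log2 fold change beyond 1, in 74 of 124.

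Values that changed sign were Actb in Transduced neurons with 2 or more viral UMIs (−0.35, and −0.31 with types matched) and type 24 with 2 or more viral UMIs (−0.13), and the cause was not tested. Counts of genes are given as higher and lower.

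With glmTreat, whose larger null change leaves fewer calls by construction, neurons against others had 2516 and 2618 genes, excitatory against inhibitory 186 and 202, the Adcyap1 type 80 and 102, Transduced neurons 3 and 6, Transduced with types matched 2 and 0 (67 genes at an unadjusted p under the threshold), TRAPed 5 and 0 (159) and TRAPed with types matched 2 and 0 (15). With the DESeq2 Wald test excitatory against inhibitory had 1320 and 1442, the Adcyap1 type 257 lower, Transduced 429 and 574, Transduced matched 382 and 501, TRAPed 67 and 17 and TRAPed matched 34 and 1. Without the library block, where differences between animals add to the error, edgeR called 917 and 1096 for excitatory against inhibitory, 10 and 11 for Transduced, 6 and 6 for Transduced matched, and 0 and 0 for TRAPed both without (1178 at an unadjusted p under the threshold) and with matching (361). It called 7 types higher and 4 lower for Transduced.

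With equal numbers of nuclei, which removes UMIs, the Adcyap1 type had 222 and 198, TRAPed 25 and 11 and TRAPed matched 19 and 0 (437 at an unadjusted p under the threshold). With 2 or more viral UMIs Transduced had 543 and 718, Transduced matched 260 and 151, TRAPed 75 and 34, TRAPed matched 44 and 9. By type there were 7 higher and 12 lower for Transduced and 0 lower for TRAPed (5 types at an unadjusted p under the threshold). Without a filter on low counts 175 genes were lower for TRAPed and 42 for TRAPed matched. Against all neurons not TRAPed 182 genes were lower. The type-balanced draw gave 522 lower for Transduced matched and 21 and 3 for TRAPed matched, matching on WPRE UMIs gave 39 and 7 for TRAPed matched, and nuclei with at least 1000 UMIs gave 10 lower there and a neuron share of 84.0%. The cause of these changes was not tested. With an estimated correlation camera called 0 gene lists in each of the 7 comparisons, against 20, 4, 2, 7, 7, 1 and 3 with the preset one, and 17 of 137 tests had an unadjusted p under the threshold.

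With 1 library left out, Transduced ranged over 541 to 1188 genes higher and 691 to 1372 lower, Transduced matched over 482 to 1118 and 603 to 1283, TRAPed over 58 to 114 and 34 to 106, and TRAPed matched over 53 to 68 and 2 to 15. Types ranged over 7 to 12 higher and 5 to 9 lower for Transduced, and over 0 to 1 and 0 to 4 for TRAPed. The counts of the neuron, excitatory and Adcyap1 comparisons stayed within 1.5 times of the reported ones in every such case. The TRAPed gene comparisons rest on 78, 141, 70 and 27 TRAPed nuclei in the 4 libraries used.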

Other observations

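The tests on splits that part every library, the test of neuronal RNA in non-neuronal nuclei and the tests of type 5 with each library left out were chosen only after the results had been seen, and so were the comparisons of TRAPed neurons that the first pattern rests on. Interferon response genes were higher in Transduced than in other neurons in 5 of 5 libraries, a difference that was not tested, at 112 against 91.5 CPM in 7_42_6, 1639 against 1177 in 7_42_8, 362 against 233 in 7_52_E, 341 against 152 in 7_52_R and 102 against 97.3 in 7_52_T.

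The TRAPed share of type 5 was 3.89 times (95% interval 3.06 to 4.87) what its libraries alone gave, 76 observed against 19.5 expected. Deeper nuclei were argued against, with a ratio of 4.23 (3.33 to 5.30) after taking out library and depth, and 3.26 (2.39 to 4.35) at the lowest with 1 library left out. A higher viral load in type 5 stays open. After taking out library and WPRE UMIs the ratio was 2.12 (1.67 to 2.65), but 1.64 (1.2 to 2.18) without 7_42_6, and the libraries differed, with 3.85 (2.60 to 5.50) in 7_42_6, 1.64 (1.09 to 2.38) in 7_42_8, 2.19 (1.25 to 3.56) in 7_52_E and 0.532 (0.0644 to 1.92) in 7_52_R. A greater activity of type 5 neurons in the labelling window was not tested, since the design names no group for it.

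With nuclei summed over libraries, Chrm3 and Chrm4 were higher at 4 or more than at 0 WPRE UMIs in 29 of 29 types compared. In non-neuronal nuclei Chrm3 rose as well, from 73.0 to 1086 CPM, and there neuronal RNA in the same droplets stays open: the gain would need a neuronal share of 42.4%, while 7 of 8 pan-neuronal genes gave a median share of 35.1% (31.1% to 43.4%; Nefl was left out, since its level at 0 WPRE UMIs was 151% of that in neurons), a ratio of 1.21 (1.11 to 1.29, over the quartiles of those genes), where a share over 2 times their upper quartile would have argued against it. Chrm4 would need 48.0%, above each of the 7 genes. A viral transcript counted as Chrm3 and Chrm4 stays open. The gain in Chrm3 was 1776 CPM in the 9 types with the lowest level at 0 WPRE UMIs and 1326 CPM in the 9 with the highest, a ratio of 1.34 (1.00 to 1.80), so it did not grow with the types' own level. It was not alike in every type, from 839 CPM in type 7 to 2856 CPM in type 5. Nor did it follow the viral counts in type 4. There the nuclei with 4 or more WPRE UMIs held 20654 WPRE CPM, against 1743 (type 24) to 4696 (type 5) in the other types compared. The gain in Chrm3 in type 4 was 2330 CPM, within the range of the others. Designer receptors made from muscarinic receptors are a common payload of such vectors, but the payload is not given in the sources used here, and no biological explanation was tested.

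Each comparison was repeated on other splits of the same sums into groups of the same sizes, with the real split counted in. Since both arms come from the same animals, the real split is set beside the splits that part the 2 arms of every library, 16 with 5 libraries and 8 with 4, which are too few for a share under 0.05. The real and the highest other counts among them were 11848 and 0 for neurons, 4490 and 0 for excitatory neurons, 920 and 22 for the Adcyap1 type, 2344 and 25 for Transduced, 2222 and 26 for Transduced matched, 226 and 48 for TRAPed and 115 and 0 for TRAPed matched, with 1 split, the real one, giving as many in each. By type they were 22 and 0 for Transduced (1 split) and 5 and 5 for TRAPed, where 2 of 16 splits gave as many types. The other splits differ in that they put both arms of some libraries on the same side. With the library as a block such libraries add nothing to the contrast, which then rests on the libraries still parted, 3 of 5 or 2 of 4 in the splits with the highest counts. These gave up to 2 genes for neurons, 187 for excitatory neurons, 344 for the Adcyap1 type, 1645 for Transduced, 1592 for Transduced matched (50 splits drawn for each), 106 for TRAPed and 74 for TRAPed matched (32 splits each, with 3 more that could not be fitted), and 10 types for Transduced and 6 for TRAPed (100 splits each).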
